A study of Rattus norvegicus with 16 samples.

How the data were processed

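RNA was measured in liver and bone marrow of female Big Blue rats, a transgenic strain that carries reporter genes for mutation assays. The rats had been gavaged daily with 0 or 10 mg/kg/day of N-nitrosodiethylamine (NDEA), a liver carcinogen that becomes a DNA-alkylating agent after oxidation by cytochrome P450, for 28 days. Tissue was taken 3 days after the last dose. Each of the 4 groups (liver control, liver NDEA, marrow control, marrow NDEA) had 4 libraries, 16 in all. Per the labels' protocols, libraries were made with a QuantSeq kit, which reads the 3' end of polyadenylated transcripts, so a gene's count does not scale with its length. The labels name no molecular identifiers, so the floors given for genes with 0 counts cover counting error only. The labels describe separate treated rats, but do not say which cage a library's rat came from, or whether liver and marrow libraries with the same number came from one rat.

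The values used are raw counts of reads per gene, as the authors deposited them. Per the submitters' processing notes, STAR and DESeq2 were used by the authors, with no version given. The counting tool, the genome build and the annotation are not given in the sources used here, so positions below are those of the deposited table, 1 per gene, on an unnamed build. The deposited table was damaged in part. Of its 32635 lines after the header, 15579 were held as a single quoted cell, and 12 gene records were broken over 2 lines. After rejoining, 32623 gene records were read, each with 16 whole counts, and 16658 genes had 0 counts in all libraries. In 16313 records the deposited table also held 4 unnamed group totals, and in all 16313 these equalled the sums of the counts of the 4 libraries of each group, with 0 mismatches. Further unnamed columns of the authors' own comparisons have no header and were not used. Because a plain reading of the file puts stray pieces of broken lines under the count columns, the unit of these columns was recorded as other than plain counts, although the rejoined values are whole counts.

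This record decided the test. The quasi-likelihood count test planned before the data were examined was not run, and neither was the Wald test for counts planned as an alternative. Limma's voom method, which had been listed beforehand as an alternative, took its place as the main test, a choice made before any real fit was run. Each tissue was filtered, scaled and fitted alone, with treatment as the sole term. A gene was kept if it reached the CPM equal to 10 counts in the median library in at least 4 libraries and had at least 15 counts in all. Libraries were scaled by trimmed means of M values (TMM; trims of 0.3 and 0.05). Fold changes are differences of log2 CPM with a prior of 0.5 counts, and CPM values below are computed on the scaled counts of the tested genes. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The difference between tissues in the NDEA effect was tested as the treatment-by-tissue term in a fit of all 16 libraries. R 4.3.3 and limma 3.58.1 were used.

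Before the data were examined, 51 gene lists were fixed, 33 of gene programmes and 18 of cell type markers. Of their 1076 entries, 1001 (93%) were matched to a gene record by symbol, listed alias or a RefSeq table of assembly GRCr8 used for names alone; the others were not analysed here. Lists with at least 5 tested members were compared with all other tested genes by camera (two-sided, preset inter-gene correlation of 0.01), with adjustment over the lists tested in a tissue. Genes named in the text followed a rule also fixed beforehand. It took the 5 largest rises and 5 largest falls among called genes with an average log2 CPM of at least 2, an established symbol and no overlap between groups. It added up to 3 members of each of the 6 lists with the most called members, and Cdkn1a, Mdm2, Ccng1, Mgmt, Cyp2e1, Gstp1 and Mki67 whatever their values. For the tissue difference it took the 3 called genes with the largest difference in each direction, with the same limits on CPM (here averaged over all 16 libraries) and symbol, so larger differences of genes with a lower average are left out. Other list members were named as examples after their values were seen.

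The method was tested on simulated data, in 10 draws of counts, averaged because single draws varied, with the real means, library sizes and typical spread and 200 changed genes. In liver, with about 9594 genes tested, a mean of 38.9% of 2-fold and 70.6% of 4-fold changes were recovered. In marrow, with about 9130 genes tested, these means were 22.8% and 65.6%. For the tissue difference, with about 11122 genes tested, they were 4% and 33.8%. False calls made up 3.52%, 3.28% and 7.35% of all calls. A p53 list raised 2-fold was called in 10 of 10 draws in each tissue. The draws use a spread smoothed over genes and hold no shared variation between libraries, which the real marrow libraries have.

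Before averaging, replicates were compared. The chi-square of a pair's counts over genes, divided by its degrees of freedom, was 13.2 to 34.4 in liver and 16.1 to 71.3 in marrow, so no pair agreed within sampling noise. Alternatives covered the scaling, the low-count filter, the libraries in the fit, the replicate number as a block, leaving out each library, haemoglobin and mitochondrial genes left out, and the set test. Further ones were added after seeing the data: limma-trend, library quality weights, the mitochondrial share as a covariate, marrow without 2 NDEA libraries, and the tissue difference over genes tested in both tissues. Reads from near-identical paralogs (cytochromes P450 of one subfamily, glutathione S-transferases, MHC genes, sulfotransferases) may have been split or shared by the authors' counting, so single members of these families are uncertain. A few genes among those tested are not reported here; they stayed in all tests and counts, except the list of flagged tissue differences.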

Results

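Gene expression was profiled in liver and bone marrow of rats given NDEA or vehicle for 28 days, to compare the response to this nitrosamine in both tissues. Liver libraries held 5000844 to 6863592 counts and detected 10545 to 11855 genes. Their mitochondrial share of counts was 16.21% to 20.58% in control and 20.09% to 22.36% in NDEA, while the list of mitochondrially encoded transcripts was not called in liver (median log2 fold change -0.11, camera adjusted p = 0.634); this share was not tried as a covariate in liver. Marrow libraries held 2162182 to 5705705 counts and detected 9101 to 11699 genes. The shallowest was marrow control 1. Tissue-specific genes followed the labels: Alb, the gene of serum albumin, stood at 67800 CPM or more of all counts in every liver library and at 0.438 CPM or less in every marrow library. Mpo, a granule enzyme of myeloid cells, stood at 395 to 606 CPM in marrow and had 0 counts in liver. P-values of single genes measure the spread between the 4 libraries of each group. Those of camera compare a list's genes with the other genes. With the preset correlation they assume, rather than measure, how far a list's genes vary together between libraries.

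In liver, NDEA raised genes of the p53 response, and Mgmt, the enzyme that removes alkyl groups from guanine in DNA. Cdkn1a, a p53-induced inhibitor of the cell cycle (ENSRNOG00000000521, chromosome 20, position 6351458), rose from 23.5 ± 16.8 to 327 ± 47.9 CPM (SD, n = 4 each; log2 fold change 4.02, SE 0.30, limma-voom adjusted p = 2.58e-09). Mgmt (ENSRNOG00000016038, chromosome 1, position 209237233) rose from 29.6 ± 4.72 to 174 ± 8.10 CPM (log2 fold change 2.57, SE 0.19, limma adjusted p = 2.29e-09). Ccng1, a p53 target that encodes cyclin G1, rose 4.42-fold, and Mdm2, the ubiquitin ligase that degrades p53, rose 3.43-fold. In the p53 list 8 of 25 tested genes rose and 0 fell (10 rose when adjusted over the list alone), and the list was called higher (median log2 fold change 0.79, camera adjusted p = 4.43e-07; adjusted p = 0.0465 with an estimated correlation). Btg2, Phlda3, Perp, Aen and Plk2 were the other called members. In the list of direct reversal and base excision repair, Mgmt was the sole called member of 18 (camera adjusted p = 0.0394; adjusted p = 0.238 with an estimated correlation). Among homologous recombination and Fanconi genes, Fancb alone of 9 was called (camera adjusted p = 0.032; adjusted p = 0.148 with an estimated correlation). Fancb had 0 counts in the 4 controls and 3.36 ± 0.864 CPM in NDEA liver (SD, n = 4). With 0 counts in controls, Fancb could pass the filter only by being higher with NDEA. The call of the first repair list ended with the filter at 5 CPM (adjusted p = 0.11), with library totals alone (0.0574), with the replicate block (0.0614) and without control 4, NDEA 2 or NDEA 3 (0.115, 0.0578 and 0.0969). The call of the second ended with that filter (0.22), with library totals alone (0.0677), with the block (0.0614) and without control 1 or 2 (0.0622 and 0.0652).

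**Figure D1:**
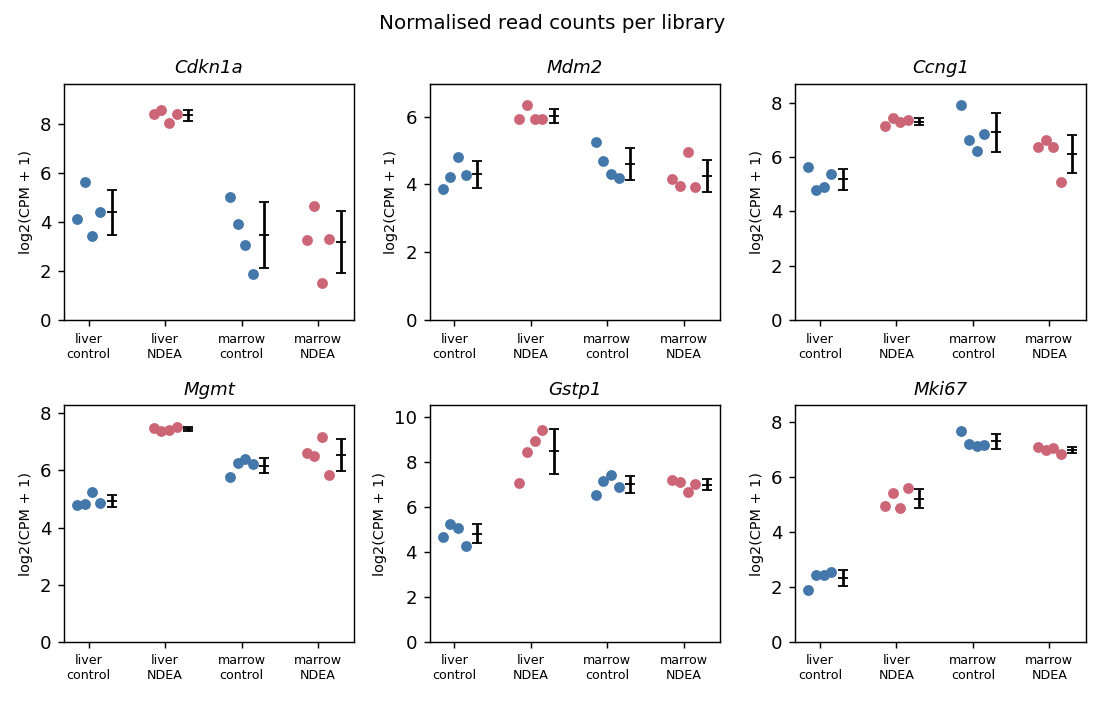
Normalised read counts of 6 genes fixed beforehand, as log2(CPM + 1), per library (points) with the mean and SD of 4 libraries (bars) for control and NDEA in each tissue. In liver the 4 NDEA libraries lie above the 4 controls for every gene shown. In marrow the groups overlap for every gene shown except Mki67, whose 4 NDEA libraries lie below the 4 controls. No gene shown was called in marrow.

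Genes of cell division rose together in NDEA liver. All 29 tested members of the cell cycle list had a higher estimate, 15 rose and 0 fell (26 rose when adjusted over the list alone; median log2 fold change 3.47, camera adjusted p = 5.26e-17), although the list's adjusted p = 0.0649 with an estimated correlation. Mki67, a marker of cycling cells, rose from 4.04 ± 0.946 to 36.5 ± 9.07 CPM (SD, n = 4 each; limma adjusted p = 3.56e-04). Cdc20, an activator of the anaphase-promoting complex, rose 12.2-fold, and Ube2c, its partner ubiquitin-conjugating enzyme, rose 7.78-fold. By the rule for named genes the largest rises were those of Cenpf, Tubb6, Sds, Gria3 and Ckap2. Tubb6, a beta-tubulin, rose 30.5-fold, and Gria3, a glutamate receptor subunit, rose 20.2-fold. The log2 fold change of Tubb6, 4.930, was 3.851 without control 4, where it had 0 counts, and 5.545 without control 2. Cenpf, a kinetochore protein, reached 40.6 ± 14.6 CPM (SD, n = 4) from 3.94 ± 6.16 CPM. The Cenpf call ended without liver control 1, 2 or 3 (adjusted p of 0.0969, 0.0551 and 0.0508), and the Ckap2 call without control 1 (0.0554). Sds, serine dehydratase, a gluconeogenic enzyme, rose 26.1-fold, to 123 ± 52.6 CPM (SD, n = 4). The log2 fold change of Sds, 4.705, was 5.456 without control 2, which stood far above the other controls. Of the immediate early and heat shock list, Egr1, Jun and Ier2 rose among 19 tested (camera adjusted p = 0.0327; adjusted p = 0.612 with an estimated correlation), and this call ended without liver control 3 or 4 or NDEA 1 or 2 (adjusted p of 0.136, 0.173, 0.159 and 0.073).

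Detoxification genes induced by the transcription factor NRF2 and markers of altered hepatocyte foci also rose. In the NRF2 list 7 of 20 tested genes rose and 0 fell (camera adjusted p = 1.29e-06), and 10 rose and 1 fell when adjusted over the list alone. Ephx1, microsomal epoxide hydrolase, rose from 417 ± 53.3 to 1644 ± 75.0 CPM (SD, n = 4 each; limma adjusted p = 3.09e-12). Gclc, of glutathione synthesis, and Nqo1, a quinone reductase, had log2 fold changes of 1.56 and 1.48. Of the foci markers, 5 of 16 tested rose and 0 fell (9 rose when adjusted over the list alone; median log2 fold change 1.17, camera adjusted p = 3.04e-07). Gstp1, the placental glutathione S-transferase that marks such foci in rats, rose 13.1-fold, and its 4 NDEA libraries spanned 135 to 690 CPM. Ephx1, Nqo1 and Akr7a3 stand on both lists, and both were also called with an estimated correlation (adjusted p = 0.0465 each). Gstm1, Gsta3 and Gstp1 rose among 18 glutathione S-transferases (median log2 fold change 0.10, camera adjusted p = 0.0218; adjusted p = 0.112 with an estimated correlation).

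Genes of hepatocyte metabolism fell on balance. Among cytochromes P450, 12 of 21 tested fell and 5 rose, the same numbers when adjusted over the list alone. The list was called lower (median log2 fold change -0.48, camera adjusted p = 2.23e-05), while its mean was 0.13. Among the 5 that rose, Cyp2c13 had 0 counts in the 4 controls and was at least 195-fold higher, against a floor of 3 counts over the group, and Cyp1a1 stood at 0.129 ± 0.171 CPM in controls and 11.4 ± 5.64 CPM in NDEA liver (SD, n = 4 each). Cyp1a2 went from 1895 ± 209 to 821 ± 172 CPM (SD, n = 4 each; limma adjusted p = 1.73e-07). Cyp2e1, the main enzyme of NDEA activation, went from 3367 ± 414 to 2448 ± 199 CPM, or 0.728-fold (SD, n = 4 each; limma adjusted p = 0.00185). Cyp2c7 and Cyp2d1 fell to 0.235-fold and 0.551-fold. In the bile acid list 9 of 20 tested genes fell and 1 rose (14 fell and 3 rose when adjusted over the list alone; median log2 fold change -0.54, camera adjusted p = 3.04e-07). The transporters Slco1b2 and Abcb11 fell to 0.479-fold and 0.535-fold, and the enzyme Akr1d1 rose 2.42-fold. In fatty acid and triglyceride synthesis 7 of 18 tested genes fell, Dgat2, Acly and Fasn among them, and 2 rose, Lpin1 and Lpin2 (median log2 fold change -0.60, camera adjusted p = 2.47e-05). These 3 lists were also called with an estimated correlation (adjusted p = 0.0465 each).

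Other hepatocyte lists were called lower with the preset correlation but not with an estimated one. For secreted proteins 12 of 26 fell and 3 rose, Apoa2 to 0.536-fold and Itih3 to 0.595-fold, while Apoa1 rose 1.67-fold (camera adjusted p = 6.58e-08; adjusted p = 0.238 with an estimated correlation). For complement 5 of 19 fell and 0 rose (3.04e-07; adjusted p = 0.0649 with an estimated correlation). For cholesterol synthesis 7 of 22 fell and 1 rose (2.00e-05; adjusted p = 0.192 with an estimated correlation). For the acute phase list 4 of 16 fell and 1 rose (1.72e-04; adjusted p = 0.188 with an estimated correlation). For hepatocyte markers 7 of 14 fell and 3 rose, Fabp1 to 0.451-fold (0.0026; adjusted p = 0.374 with an estimated correlation). For oxidative phosphorylation 2 of 27 fell (6.94e-04; adjusted p = 0.28 with an estimated correlation). For PPAR-alpha targets 1 of 23, Fabp1, fell (0.0137; adjusted p = 0.417 with an estimated correlation). For urea cycle and amino acid catabolism 7 of 27 fell, Hal, Oat and Hpd among them, and 3 rose (0.0195; adjusted p = 0.238 with an estimated correlation). The median of this list was -0.09 and its mean 0.02. With library totals alone the median was 0.03 and the call ended (adjusted p = 0.14), as did that of the PPAR-alpha list (0.0717). The urea cycle call also ended with the filter at 5 CPM (0.0514) and without control 2 or NDEA 4 (0.102 and 0.0818), and the PPAR-alpha call without NDEA 3 or 4 (0.052 and 0.0642).

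MHC class II genes, which present peptides on antigen-presenting cells, rose in NDEA liver. Of 7 tested, 5 rose (median log2 fold change 1.32, camera adjusted p = 4.14e-13; adjusted p = 0.0269 with an estimated correlation). RT1-Da rose from 189 ± 27.6 to 471 ± 29.0 CPM (SD, n = 4 each; limma adjusted p = 6.74e-08), and Cd74, the invariant chain, from 178 ± 10.4 to 422 ± 54.0 CPM (SD, n = 4 each; limma adjusted p = 2.78e-07). Markers of Kupffer cells and macrophages had a median log2 fold change of 0.02, with Marco higher and Vsig4 lower among 15 tested, and sinusoidal endothelial markers of -0.20, with 0 of 11 called. In the fibrosis and matrix list 4 of 22 rose, Col3a1, Col4a1, Fbn1 and Dcn, and Fn1 fell (median log2 fold change 0.84, camera adjusted p = 9.21e-06; adjusted p = 0.0465 with an estimated correlation). Of 13 stellate cell markers, Vim, Col3a1 and Dcn rose (camera adjusted p = 0.00344; adjusted p = 0.0649 with an estimated correlation).

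Among the large falls in liver were those of A1bg, Cyp3a9, Lifr and Cpa1. A1bg went from 765 ± 416 to 15.4 ± 10.8 CPM (SD, n = 4 each; limma adjusted p = 9.01e-05). Lifr, the receptor of leukaemia inhibitory factor, fell to 0.0491-fold, Cpa1, a carboxypeptidase, to 0.0559-fold and Cyp3a9 to 0.0295-fold. In all, limma-voom called 639 of 9668 genes, 277 higher and 362 lower, and 274 of these changed at least 2-fold (174 higher, 100 lower). With a library left out, 167 to 265 genes were called higher and 269 to 377 lower, 167 higher without control 3. Of 43 lists tested, 22 were called (11 higher, 11 lower), 8 with an estimated correlation and 21 with fry. The groups did not overlap for 12.5% of tested genes, against 2.86% by chance. Scaling by library totals alone shifted the median log2 fold change of all genes from 0.012 to 0.124, and the split to 390 higher and 239 lower.

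**Figure D2:**
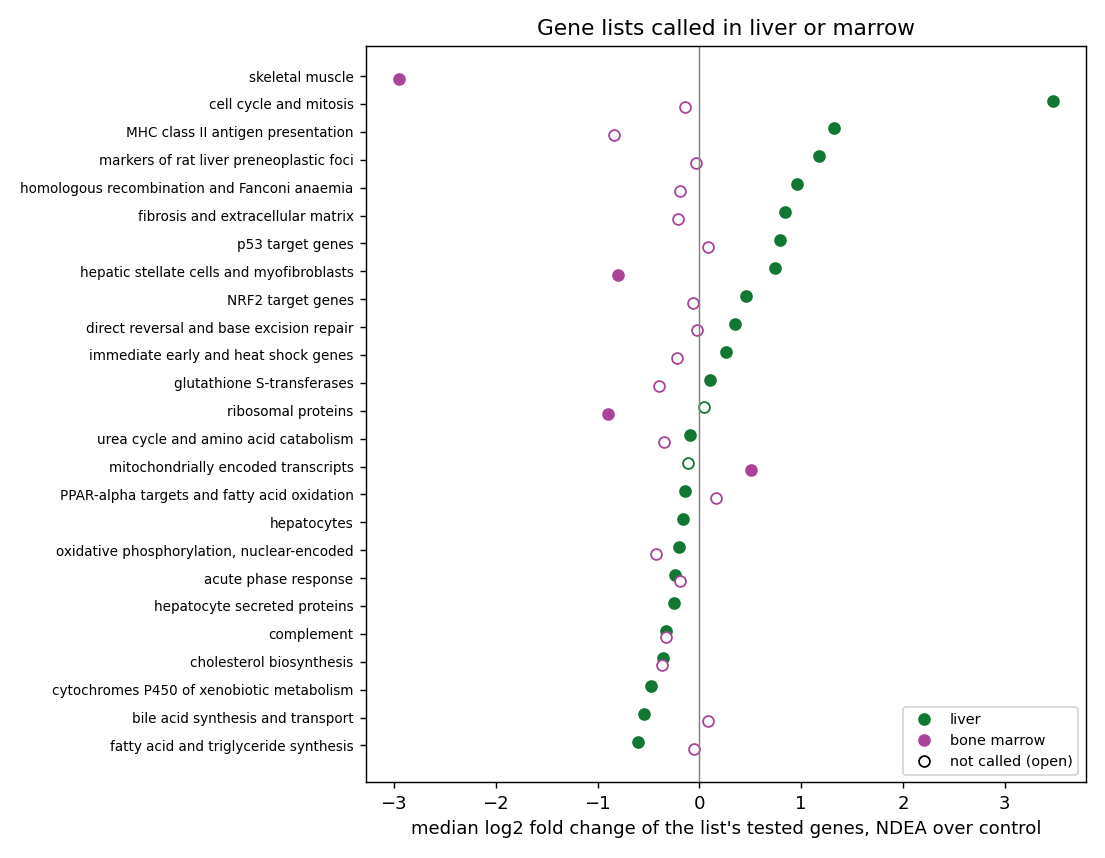
Median log2 fold change of each gene list's tested members, NDEA over control, in liver (green) and bone marrow (purple), for lists called by camera with a preset correlation in either tissue (filled points) and lists not called (open points). The cell cycle list stands at 3.47 in liver and at -0.14 in marrow; lists with fewer than 5 tested members in a tissue are not drawn.

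In bone marrow, limma-voom called 0 of 9239 genes, and the smallest adjusted p was 0.247. Limma-trend and limma-voom with quality weights also called 0. At an unadjusted p under 0.05 there were 1336 genes. These numbered 871 to 1952 with a library left out, 501 without marrow NDEA 3 and 4, and 347 with the mitochondrial share as a covariate. The groups did not overlap for 5.6% of tested genes, against 2.86% by chance. The count of called genes depended on the fit and on 1 library. With the replicate block 289 genes were called (109 higher, 180 lower), and with all 16 libraries in one fit 69. Without marrow control 3 the count was 318 (111 higher, 207 lower). Without control 3, Acta1, Tnnc2, Rpl11, Rps23, Rpl3, Mt-co2, Myl9, Col1a1, Pf4, Cox5b, Atp5po and Uqcrfs1 were among those called, with adjusted p from 0.00774 for Rpl11 to 0.0475 for Col1a1. The p53 targets of the liver were not called: Cdkn1a stood at 13.9 ± 12.6 CPM in control and 10.8 ± 9.27 CPM in NDEA marrow (SD, n = 4 each; limma adjusted p = 0.97), Mdm2 at 24.5 ± 8.88 and 18.8 ± 7.39 CPM, and Ccng1 at 132 ± 73.5 and 74.1 ± 28.4 CPM. Mgmt stood at 71.4 ± 12.4 and 96.8 ± 36.5 CPM, and Mki67 at 156 ± 30.6 and 125 ± 9.38 CPM. Gstp1 had a log2 fold change of -0.02 (SE 0.24). Cyp2e1 had 0 counts in marrow.

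Of 47 lists tested in marrow, 4 were called with the preset correlation and 0 with an estimated one. Skeletal muscle genes were lower (9 of 9 estimates, median log2 fold change -2.95, camera adjusted p = 4.76e-06; adjusted p = 0.761 with an estimated correlation), with 5 lower when adjusted over the list alone. Acta1, skeletal actin, stood at 70.3 ± 47.7 CPM in control and 10.3 ± 2.80 CPM in NDEA marrow, and Tnnc2 and Tnni2, troponins of fast muscle, had log2 fold changes of -3.32 and -5.62. Ribosomal protein genes were lower (median -0.90, camera adjusted p = 4.76e-06; adjusted p = 0.761 with an estimated correlation), 16 of 23 when adjusted over the list alone; Rpl11, Rps23 and Rpl3 had log2 fold changes of -1.48, -1.83 and -1.06. Mitochondrially encoded transcripts were higher (12 of 12 estimates, median 0.51, camera adjusted p = 7.45e-04; adjusted p = 0.761 with an estimated correlation), Mt-co2, Mt-cyb and Mt-nd1 at 0.70, 0.59 and 0.60. Stellate and myofibroblast markers, which marrow stroma also expresses, were lower (9 tested, median -0.80, camera adjusted p = 0.0424; adjusted p = 0.761 with an estimated correlation), with Dcn, Myl9 and Col1a1 at -2.82, -0.80 and -0.85. The list of marrow stroma, osteoblasts and adipocytes itself was not called (15 tested, 5 estimates higher and 10 lower, median -0.45, camera adjusted p = 0.431). Of lists not called, megakaryocyte genes had a median of -0.55 (camera adjusted p = 0.0774), Pf4, Gp9 and Clec1b at -1.18, -0.86 and -1.07, and nuclear-encoded oxidative phosphorylation -0.43 (0.0774), Cox5b, Atp5po and Uqcrfs1 at -0.85, -0.93 and -1.58. The call of the mitochondrial list ended without marrow NDEA 4 (adjusted p = 0.0519) and without NDEA 3 and 4 (0.734). That of the stellate list ended without control 2, NDEA 2 or NDEA 4 (0.0995, 0.0578 and 0.12), without NDEA 3 and 4 (0.402), with the filter at 5 CPM (0.0603) and with library totals alone (0.0547). The mitochondrial share of counts was 6.41% to 13.01% in control and 8.37% to 15.78% in NDEA marrow, and NDEA 3 and 4 detected the fewest genes (10144 and 9101).

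**Figure D3:**
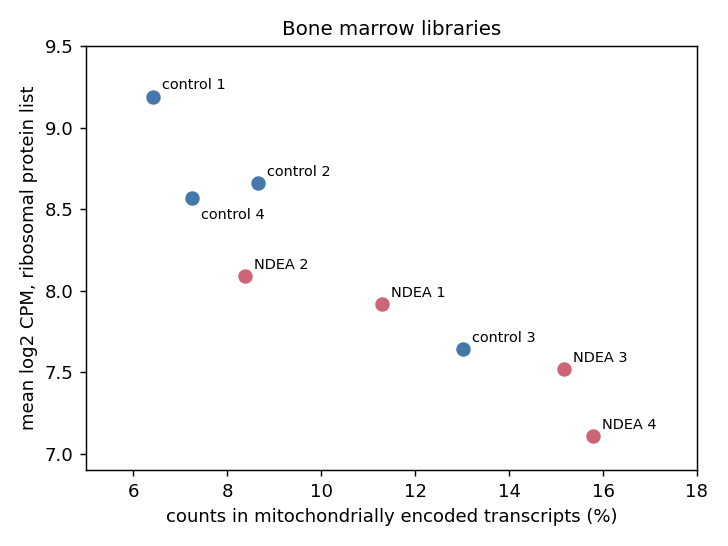
Mean log2 CPM of the ribosomal protein list against the percentage of counts in mitochondrially encoded transcripts, for the 8 marrow libraries (blue control, red NDEA; points are single libraries). Control 3, at 13.01%, lies among the NDEA libraries; control 1, at 6.41%, has the highest ribosomal protein level.

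The NDEA effect differed between tissues for 257 of 11261 genes (limma-voom, treatment-by-tissue term), 233 with a liver effect above the marrow effect and 24 below it. Of the 257, 193 passed the filter of both tissues, 42 that of liver alone, 13 that of marrow alone and 9 neither. Genes outside the 193 rest on low counts in a tissue where they failed the filter. In liver, 139 of the 257 were also called. The median difference over all genes was 0.316, and 0.191 to 0.401 under the other scalings. That shift by itself favours differences above 0 in the split of 233 and 24. Mybl2, a transcription factor of the cell cycle, had 0 counts in the 4 liver controls and 11.8 ± 1.96 CPM in NDEA liver (SD, n = 4), at least 90.5-fold higher against a floor of 3 counts over the group; its log2 fold change in marrow was -0.04. Cdk1 and Rbp7 had differences of 6.10 and 5.74, and Kctd6, Fzd4 and Coq10a of -4.85, -2.66 and -2.32. The Cdk1 call ended when any of 9 libraries was left out, the 4 liver controls among them (adjusted p of 0.0816, 0.0663, 0.0827 and 0.121). The other 5 were liver NDEA 2 and 4 and marrow control 1, 2 and 4 (0.0619, 0.0624, 0.0602, 0.0635 and 0.0707). The Fzd4 call ended without marrow control 4 (0.0726), and the Coq10a call without liver control 4 or marrow control 2 or 4 (0.054, 0.0664 and 0.0502). The calls of Cdk1, Kctd6 and Fzd4 also ended with the replicate block (0.0633, 0.052 and 0.0857), those of Cdk1 and Rbp7 with limma-trend (0.0604 and 0.0594), that of Cdk1 with no filter (0.0502), and those of Kctd6 and Coq10a without marrow NDEA 3 and 4 (0.0554 and 0.106). Cdkn1a differed by 4.04, Mgmt by 2.28, Gstp1 by 3.79 and Mki67 by 3.49. The count fell to 102 without liver control 4 and 163 without liver control 3, and rose to 509 without marrow control 3; without marrow NDEA 3 and 4 it was 88. As marrow had 0 calls, the 217 higher and 217 lower liver calls among 7971 genes tested in both tissues shared 0 genes with it, where 0 are expected. Of these 434 liver calls, 203 (46.8%) had the same sign in marrow.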

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

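The tests of the MHC class II genes were chosen after their values were seen. The tests of depth, RNA quality and muscle were written down before their results, for patterns first seen in these data; the condition on the SE in the muscle test was added after its value was seen. Of 132 groups of 4 values examined, 13 held a library whose gap to the nearest value was large against the range of the 4 (Dixon's test). Chance gives about 6.6 for independent normal values, which these need not be. Where the other 3 lie close together, a small difference is flagged too.

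In liver controls, Sds stood at 22.1 CPM in control 2 against 2.21 to 2.97 in the others, Hal at 242 CPM in control 4 against 189 to 197, and Mgmt at 36.6 CPM in control 3 against 26.5 to 28. In NDEA liver, Cpa1 stood at 66.1 CPM in NDEA 3 against 4.89 to 9.89, Akr1d1 at 844 CPM in NDEA 1 against 824 to 827, Hal at 63.7 CPM in NDEA 1 against 92.3 to 98, and Mdm2 at 79.2 CPM in NDEA 2 against 59.3 to 59.8. In marrow controls, Tnnc2 stood at 43.3 CPM in control 3 against 17.5 to 19.7. Marrow control 1, the shallowest library, stood apart in Clec1b (138 CPM against 39.9 to 50.6), Mki67 (202 against 136 to 145) and the haemoglobin share (21.235% against 25.452% to 25.837%). In NDEA marrow, Dcn stood at 12.5 CPM in NDEA 1 against 0.791 to 2.7, and Mdm2 at 29.7 CPM in NDEA 3 against 14.2 to 16.7.

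The difference between NDEA and control libraries was not the same in liver and marrow for the genes named here, by limma's treatment-by-tissue term. For Tnni2, a muscle gene, this may come from muscle carried over with the marrow rather than from NDEA. The log2 difference, liver minus marrow, was 7.14 for Mybl2, 6.84 for Tubb6, 6.14 for Tnni2, 6.10 for Cdk1, 5.74 for Rbp7, 5.57 for Gria3 and 5.42 for Cenpf. It was 4.26 for Ckap2, 4.18 for Cdc20, 4.04 for Cdkn1a, 3.98 for Dcn, 3.79 for Gstp1, 3.49 for Mki67 and 3.17 for Ube2c. For Ccng1, Mgmt and Mdm2 it was 2.93, 2.28 and 2.15. It was negative for Kctd6 (-4.85), Cyp3a9 (-4.77), Fzd4 (-2.66) and Coq10a (-2.32). The value of Mybl2 rests on the prior of 0.5 counts, as its 4 liver controls had 0 counts, so its place above Tubb6 is not shown. Tnni2 did not pass the filter in liver, nor Gria3 and Cyp3a9 in marrow, so their values rest on low counts there. Of 100 draws of treatment labels within each tissue, 1, the real one, gave as many genes as the 257 found, and the highest of the others was 146. Such draws remove the NDEA effect from both tissues. They argue against this count arising by chance with no effect in either tissue, and do not test an equal effect in both. With a library left out the count was as low as 102, under that 146.

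In NDEA marrow, ribosomal protein transcripts were lower and mitochondrially encoded ones higher, on the preset correlation alone. With every library thinned to 2162182 counts, the ribosomal median log2 fold change was -0.88 (-0.93 to -0.84 over 20 thinnings, -0.90 unthinned). Random thinning keeps each gene's expected share of counts, so a median near the unthinned one was likely whatever the cause. This test therefore cannot decide on a difference in depth. RNA quality that varies between libraries may account for part of the ribosomal and mitochondrial pattern. Within groups, the mitochondrial share and the mean ribosomal protein level had r = -0.91 over 8 libraries (exact permutation p = 0.00347, Spearman's rho -0.90, exact permutation p = 0.0104, 1 relation computed). Without the 2 libraries farthest from the median share, r was -0.78. With that share as a covariate the ribosomal median moved from -0.90 to -0.28, and the list was still called with the preset correlation (camera adjusted p = 6.27e-04). What was left was not tested with an estimated correlation, under which the list was not called even without the covariate (adjusted p = 0.761), so whether the share accounts for all of it stays open. An effect of NDEA on marrow stays open, since NDEA 3 and 4 have the highest shares.

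Skeletal muscle transcripts had lower estimates in NDEA marrow, called with the preset correlation but not with an estimated one (adjusted p = 0.761) or with fry (adjusted p = 0.177). In the main fit 0 of the 9 genes were called, while Acta1 and Tnnc2 were called without control 3. The summed level of the 9 genes was 164, 168, 554 and 250 CPM in controls 1 to 4 and 62.9 to 80.5 CPM in NDEA libraries. Muscle carried over in unequal amounts could give this, and would make the muscle genes vary together within groups. Their mean pairwise r within groups was 0.14 (jackknife SE 0.15), under the bound of 0.2 set beforehand. The value lies under that bound by less than its SE, a condition added after the value was seen. For random sets of 9 genes, 95% lay under 0.18. Some muscle genes had low counts in NDEA libraries, such as Tnni2 at 0 to 1.62 CPM and Tnnc2 at 1.62 to 2.97 CPM. Counting noise lowers such an r, so the bound could not decide. Carry-over and an effect of NDEA therefore cannot be told apart.

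MHC class II transcripts were higher in NDEA liver, with a median log2 fold change of 1.32. A lower share of hepatocytes would raise macrophage and endothelial markers alike, and more macrophages of all kinds would raise theirs. The higher of the medians of these lists was 0.02, that of the macrophages, which argues against both as the whole cause. Stellate and cholangiocyte markers had medians of 0.74 and 1.33, which go with a lower share of hepatocytes, though the cholangiocyte list was not called (camera adjusted p = 0.0919) and the stellate list not with an estimated correlation (adjusted p = 0.0649). A lower share alone would not leave the macrophage and endothelial lists behind, unless those cells or their markers also fell, which was not tested. More B cells could not be tested, with 3 mature B cell markers measured. More of another cell type with MHC class II, such as dendritic cells, and induction in cells already present stay open, as untested.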

How the results depend on the processing

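Alternatives with limma-trend, quality weights, the mitochondrial share as a covariate, genes tested in both tissues, and marrow without NDEA 3 and 4 were chosen after seeing the data; the alternatives with DESeq2 were not run. Where no value below shows a cause, the cause was not tested. In liver, the count of 639 genes was 439 to 600 with a library left out. Of the 35 splits of the 8 libraries, 1, the real one, gave as many (highest other 0, also for the 274 genes changed 2-fold, again 1 of 35). That argues against chance but does not exclude it, as 35 splits allow no exact permutation p under 0.0286. With no filter, 418 genes changed at least 2-fold, of 14299 tested. Of the 22 liver lists, 8 were called with an estimated correlation. Fry called 21 lists, 19 of them among the 22, and ended the calls of PPAR-alpha targets (adjusted p = 0.128), immediate early and heat shock genes (0.326) and hepatocyte markers (0.089). Of the splits, 2 of 35 gave 22 lists (highest other 22), so chance is not excluded for that count. The other of these splits exchanged control 3 and NDEA 1. In marrow, the 0 genes became 2 with no filter (2 of them 2-fold), 69 with all 16 libraries in one fit (54 at 2-fold), 1 with the mitochondrial share as a covariate (1 at 2-fold), and 0 to 318 with a library left out (0 to 303 at 2-fold), 318 without control 3. All 35 of 35 splits gave at least 0, and the highest other gave 531 (351 at 2-fold), by setting control 3, NDEA 1, NDEA 3 and NDEA 4, the libraries with the highest mitochondrial share, against the rest. That points to a structure of the samples. The 4 marrow lists became 0 with an estimated correlation and 0 with fry, and 2 to 8 with a library left out (8 without control 3, 2 without NDEA 4); 8 of 35 splits gave 4 or more (highest other 6), so chance is not excluded. Marrow Cdkn1a, at 0.077 with an SE of 0.736, was -0.027 with all 16 libraries, -0.328 with limma-trend and -0.685 to 0.704 with a library left out. Marrow Gstp1, at -0.024, was 0.032 with quality weights, 0.135 without NDEA 3 and 4 and -0.163 to 0.099 with a library left out. With the mitochondrial share as a covariate, Mt-nd1 was -0.009 and the mitochondrial list lost its call (adjusted p = 0.422), as the covariate removes that share. The 257 tissue differences became 88 without marrow NDEA 3 and 4 (fewer samples) and 102 to 509 with a library left out: 163 without liver control 3, 102 without liver control 4 and 509 without marrow control 3. With the 5 CPM filter marrow again had 0 calls, which by itself sets the overlap of calls to 0. The liver genes named by the rule kept their direction under each alternative. A call ended in 4 cases, each with a library left out and each for Cenpf or Ckap2. Other genes named in the text were not rerun one by one. Folds in liver moved by more than 1.5 times with a single library left out for Cenpf, Tubb6, Sds, Ckap2, Ube2c, A1bg and Cpa1, and the tissue differences of Cdk1, Rbp7 and Kctd6 did so too.

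Over all genes, replicate numbers showed no pairing of the samples: same-numbered control and NDEA deviations correlated at -0.01 to 0.01 in liver and -0.01 to 0.06 in marrow. Pairs with different numbers correlated at -0.03 to 0.04 in liver and -0.22 to 0.16 in marrow. A factor shared by same-numbered libraries that acts on part of the genes could be missed by this check, so such pairing is not excluded. With the replicate number as a block, 732 genes were called in liver, 289 in marrow (184 at 2-fold) and 145 for the tissue difference, 9 lists were called in marrow and 20 in liver, where both repair lists lost their calls (adjusted p = 0.0614 each), and marrow Cdkn1a was -0.075.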

Other observations

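The test of sex-biased genes was chosen after the largest liver changes were seen, and written down before the single values of the genes it used were seen. Counts of called genes in lists that hold some of these genes, such as the P450 list, had been seen by then.

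Several gene groups of the liver held called members while the list itself was not called. Of the list of gluconeogenesis and glycolysis, 6 of 24 tested genes fell and Sds rose (median log2 fold change 0.05, mean 0.20, test lower, camera adjusted p = 0.535). Of genes of the pericentral zone, Rhbg and Gstm1 rose and 4 of 14 fell (0.136), and of the periportal zone 3 of 18 rose and 6 fell (0.116). Rhbg, an ammonium transporter, rose 16.7-fold. Of interferon response genes Cxcl9, Psmb9 and Tap1 rose among 25 tested (0.389). Of glucuronosyltransferases and sulfotransferases 3 of 9 rose and Sult2a2 fell (0.509). Cholangiocyte and progenitor markers had a median of 1.33, with 0 of 8 called and 4 higher when adjusted over the list alone (0.0919). The lists of nucleotide excision repair, mismatch repair and the circadian clock held 0 called genes.

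In marrow, where 0 genes were called, markers of blood cell types had lower medians in several lists, none of them called by camera. The median log2 fold change was -0.89 for early neutrophil genes (10 tested, camera adjusted p = 0.0996), -0.35 for monocytes (12, 0.0942), -0.33 for erythroid cells (20, 0.139), -0.55 for T and NK cells (18, 0.385) and -0.14 for late neutrophils (14, 0.608). Plasma cell genes went the other way (0.48; 6, 0.597), and the median over all marrow genes was -0.096. MHC class II genes, higher in liver, had a median of -0.84 in marrow (7, 0.139). The p53 list had a median of 0.08 (23, 0.608) and the cell cycle list of -0.14 (31, 0.804). The haemoglobin share of counts was 21.235% to 25.837% in controls and 16.980% to 22.090% in NDEA marrow.

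A hypothesis from the liver data is that NDEA may shift sex-biased liver genes of these female rats from the female towards the male pattern. It arose because A1bg, Cyp3a9, Cyp2c7, Prlr, Srd5a1 and Akr1b7, known to be higher in females, were seen among the falls, and Hsd11b1, higher in males, among the rises. It was tested on 13 other genes of known bias whose single liver values had not been seen, of which 11 were tested. Of these, 9 moved in the male direction and 8 were called, with 0 called in the other direction. Limma's fry test with signed genes gave p = 9.12e-04 (4.34e-04 to 0.00401 with each library left out), and an exact permutation test of their mean signed statistic, two-sided and added after that result, gave p = 0.0286. That is the smallest that the 35 splits of the 8 libraries allow (3.67 for the real split, 1.82 at most for the others). Cyp2c12, the female-specific steroid hydroxylase, went from 505 ± 116 to 209 ± 48.6 CPM (SD, n = 4 each; limma adjusted p = 1.30e-05), and Cux2, a female-biased regulator, from 24.4 ± 4.53 to 5.23 ± 2.47 CPM (SD, n = 4 each; limma adjusted p = 0.00228). Cyp2c13 and Sult1e1, higher in males, had 0 counts in the 4 controls and were at least 195-fold and at least 63.5-fold higher with NDEA, against a floor of 3 counts over the group. With 0 counts in controls these 2 could pass the filter only by being higher with NDEA. In a test without them, added after these results, 7 of 9 moved in the male direction and 6 were called, with exact permutation p = 0.0286 (two-sided; 3.53 for the real split, 1.94 at most for the others). Slco1a1 and Bcl6, male-biased, had log2 fold changes of -0.44 and -0.34 and were not called. Reads shared between Cyp2c paralogs were not excluded. Fry asks whether these genes move on balance, not whether they move more than others, and a general loss of hepatocyte expression, which would lower the female-biased genes too, would not raise the male-biased ones.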
